A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

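RNA of Saccharomyces cerevisiae was measured on 8 Agilent 2-colour arrays. Per the labels, 3 samples were taken at the start of a fermentation assay (T0h) and 5 after 6 h (T6h), from cells grown beforehand in repeated batches of rich glucose medium. The T0h samples were PE-2, JP1 and CAT-1, diploid yeasts isolated from Brazilian mills. The T6h samples were 2 of JP1, 2 of CAT-1 and 1 of BY4741, a laboratory strain. Per the labels, each sample was labelled with Cy5 (red) and hybridised against BY4741 RNA of T0h labelled with Cy3 (green). The labelling notes mention a dye swap among industrial strains, but no array has its dyes swapped per the labels. The samples therefore share 1 reference, and PE-2 was seen at T0h alone and BY4741, as a sample, at T6h alone.

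Per the file headers, the scanner images were quantified by Agilent Feature Extraction 10.10.1.1, and the spot signals and local backgrounds are intensity values (brightness of pixels). The deposited scanner files also hold processed signals, which are intensity values after the software's own background subtraction and dye normalisation, and a log ratio that is the log10 of red over green processed signal. Their remaining columns used here are marks of the software for spots that are well above background, uneven, outlying or saturated, in no physical unit (other). The authors' processing notes name limma without a version. The unit of the deposited value table is not stated (other), though some of its columns followed the log2 ratios of an array with slopes of up to 0.9998. Several of its columns did not follow the array they are named for, so it entered no comparison. All values follow the names of the scanner files. Some columns followed the mean of a pair of arrays, which wrong file names cannot account for. For the others, whether the files or the table's columns are misnamed is not given. The scanner files hold no mean signal, so the median signal was used where the plan had named the mean.

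Spots marked uneven or outlying in either channel were left out. Signals were background-corrected by normexp with an offset of 50 and normalised within each array by loess, with control spots given no weight, in limma 3.58.1 under R 4.3.3. The array carries 6256 gene probes, 1 for each gene, in 2 spots each, whose log2 ratios were averaged. Probes well above background in either channel on at least 3 arrays were kept, which left 5938. Systematic names were given symbols from the reference gene table, in which 5756 were found and 500 were not. Genes are given by symbol, and their order along the chromosomes was taken from the positions in that table.

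All comparisons used limma's moderated test, which was two-sided, with Benjamini-Hochberg adjustment over the 5938 genes and a threshold of 0.05 on the adjusted p. There were 6 of them. The first set T6h against T0h over all 8 arrays. The next took time in JP1 and CAT-1 with strain as a term. Another tested the 3 T0h ratios against 0, which sets the industrial strains against the BY4741 reference. The others set JP1 and CAT-1 against BY4741 at T6h, CAT-1 against JP1 with time as a term, and the time change of CAT-1 against that of JP1. The single BY4741 array at T6h gives its change from the BY4741 reference as values without a test, and its list medians were set against 10000 random lists of like intensity. A test of the time change of JP1 and CAT-1 against that of BY4741 was added after the data were seen.

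The comparisons, the 37 gene lists and the rule for naming genes were fixed before the data were examined. The lists, written from textbook knowledge, cover central carbon metabolism (glycolysis and ethanol formation, TCA cycle, glyoxylate cycle, oxidative phosphorylation, hexose transporters, sucrose and maltose use, trehalose and glycogen, glycerol, alcohols and aldehydes). Further lists cover amino acid synthesis, sulfur, nitrogen catabolite repression, the asparaginase II cluster, thiamine, pyridoxine, phosphate, iron, copper and zinc. Others cover ribosomal proteins, ribosome biogenesis, heat shock, oxidative stress, ergosterol, seripauperins, cell wall, flocculation, sodium pumps, drug export, peroxisomes, histones, aquaporins and autophagy. The last are the BY4741 deletion markers, the a-, alpha- and haploid-specific genes and meiosis. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry (on balance, and mixed) as alternatives. Counts of members are given over all genes and adjusted over the list alone.

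The rule for naming took, per comparison, the 10 genes with the largest difference each way among those that passed, had a standard name and did not overlap between groups. It added the 4 passing members with the largest difference of each called list, or list with at least 2 passing members, and the deletion markers and mating-type genes. Where fewer than 10 passed, the rest are values and not changes. The text prints 162 results of that rule. A gene not well above background in a whole group is given as a bound on its fold. It was computed against the lowest signal marked well above background, from channel signals after quantile scaling between arrays, background-subtracted with and without median scaling, and processed with and without quantile scaling. The lowest of these and of the fitted fold is given, a choice made after the data were seen.

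Arrays give no counts, so their number and their signal over background limit the precision. In simulated data with the same layout, changes of 2 on the log2 scale were recovered at 79% in the comparison over all arrays, 57% in JP1 and CAT-1 over time, 90% at T0h, 67% between CAT-1 and JP1, and 0% in the comparison with BY4741 at T6h and in the difference of time changes. The simulation changed 200 genes and drew independent noise for each array, with the same spread on both slides. These shares may therefore not hold for the real arrays. The alternatives were no background subtraction, the software's processed signals, median centring, quantile scaling between arrays, no or a strict filter on dim probes (679 genes), outlying spots kept, another variance prior, a 2-fold minimum, strain terms, replicate number as a block, slide as a block or slide 1 alone, and each array left out in turn. The red channel alone and the averaging of arrays of 1 strain at T6h were added after seeing the data. Exact permutation of the group labels was run for single genes over all 8 arrays.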

Results

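The 8 arrays measured the expression of yeast genes at the start of a fermentation assay (T0h, 3 samples) and after 6 h (T6h, 5 samples). The title places the assay in ethanol production from sugarcane. PE-2, JP1 and CAT-1 are industrial diploid strains, and BY4741 is a haploid laboratory strain of mating type a that lacks working copies of HIS3, LEU2, MET17 and URA3. Every value is a log2 ratio to the BY4741 T0h reference. The 6 arrays of slide 1 had 89.9% to 91.3% of gene probes well above background in the green reference channel. On slide 2, which held JP1 T6h replicate 4 and CAT-1 T6h replicate 5, this was 20.8% and 11.2%. In the red sample channel it was between 81.9% and 98.3% on all arrays. Median red signals were lowest for CAT-1 at T6h, at 60 and 83, and highest for PE-2 at T0h, at 1360. Spots of the same probe gave Spearman correlations of log ratios of 0.948 to 0.978 on slide 1, and of 0.637 and 0.702 on slide 2. The deposited design calls the samples biological replicates. They are different strains in part, so the p-values measure the spread between these arrays. Across genes, which are not independent replicates, log ratios correlated at 0.670 to 0.790 between T0h arrays, 0.487 to 0.793 between T6h arrays and 0.0828 to 0.302 across times.

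Yeast at 6 h of fermentation expressed the genes of sugar breakdown far more strongly than at its start, and those of respiration less. The enolases ENO2 (YHR174W) and ENO1 were higher by 7.06 ± 0.45 and 7.0 ± 0.59 on the log2 scale (SE, 5 arrays against 3; limma adjusted p 1.87e-05 and 3.15e-05). PDC1, the main pyruvate decarboxylase, rose by 6.62 ± 0.48, and CTR3, a high-affinity copper transporter, fell by 6.53 ± 0.49. Of the 5938 genes tested, 577 rose and 352 fell, of which 854 changed at least 2-fold, and 1819 had an unadjusted p under the threshold. The comparison asked what changes between the start and 6 h of fermentation, with PE-2 at T0h alone and BY4741 at T6h alone.

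Of 21 genes of glycolysis and ethanol formation, 19 rose and 0 fell, also when adjusted over the list alone (median 4.37; camera adjusted p 2.77e-21, but adjusted p = 0.0942 with an estimated correlation). They include TDH1 (6.37), PGK1 (5.62), the pyruvate kinase gene CDC19 (5.58), GPM1 (5.53) and the alcohol dehydrogenase gene ADH1 (4.79). Hexose transporters HXT3 and HXT1, of low affinity, rose by 3.90 ± 0.77 and 3.19 ± 0.53. HXT5, a transporter of slowly growing cells, fell by 4.84 ± 0.52. Of 40 genes of oxidative phosphorylation, 33 fell and 1 rose, or 37 and 1 adjusted over the list alone (median -1.79; camera adjusted p 1.06e-23, but adjusted p = 0.206 with an estimated correlation). The riser was COX5B, the form of cytochrome oxidase subunit used at low oxygen (3.55 ± 0.47). Its aerobic counterpart COX5A fell by 3.88 ± 0.28, COX4 by 3.32 and COX6 by 3.10. The TCA cycle had 11 of 17 members lower and 0 higher, or 12 adjusted over the list alone, with SDH2 at -3.15, ACO1 at -2.81 and CIT3 at -3.47 (list median -1.64; camera adjusted p 5.28e-07, but adjusted p = 0.420 with an estimated correlation).

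Many genes for the use of carbon sources other than sugar fell. In the glyoxylate cycle and gluconeogenesis, 13 of 19 fell and 1 rose, or 16 and 1 adjusted over the list alone (median -2.45; camera adjusted p 1.60e-10, but adjusted p = 0.351 with an estimated correlation). FBP1 and PCK1, enzymes of gluconeogenesis, were at -4.26 and -3.92, JEN1, a lactate transporter, at -4.72, and ADY2, an acetate transporter, at -4.37. Of 25 peroxisomal fatty acid oxidation genes, 12 fell and 0 rose, or 13 adjusted over the list alone (median -1.05; camera adjusted p 5.28e-07, but adjusted p = 0.420 with an estimated correlation). YAT2, which makes carnitine esters, was at -4.0. CHA1, an enzyme that breaks down serine, was at -4.85, and RGI2, SPG4 and SIP18, linked to respiratory growth, stationary phase and drying, were at -4.42, -4.10 and -4.18.

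Many amino acid and sulfur genes rose. Of 62 amino acid synthesis genes, 32 rose and 3 fell, or 41 and 4 adjusted over the list alone (median 1.46; camera adjusted p 1.62e-12, but adjusted p = 0.351 with an estimated correlation). BAT1, an aminotransferase for branched-chain amino acids, was at 4.79, HOM2 at 3.76 and ILV3 at 3.66. This list's median was -0.84 under the strict filter on dim probes, which left 8 members. Of 36 sulfur and methionine genes, 20 rose and 0 fell, or 25 adjusted over the list alone (median 1.97; camera adjusted p 1.79e-10, but adjusted p = 0.351 with an estimated correlation), with CYS3, of cysteine synthesis, at 5.75 ± 0.42, MET28 at 3.70 and MET2 at 3.59. Heat shock proteins and chaperones had 21 of 34 members higher and 3 lower, or 24 and 4 adjusted over the list alone (median 2.11; camera adjusted p 8.86e-09, but adjusted p = 0.351 with an estimated correlation). BTN2, SSA4 and the small chaperone gene HSP26 were at 4.90, 4.30 and 4.08. Of 30 seripauperin and anaerobic mannoprotein genes, 19 rose and 0 fell, or 25 adjusted over the list alone (median 1.20; camera adjusted p 7.31e-11, but adjusted p = 0.420 with an estimated correlation), such as TIR3 (2.96) and TIR1 (2.40).

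Ribosome biogenesis had 18 of 108 members lower and 0 higher, as also adjusted over the list alone, such as NSA2 at -1.40 (median -0.60; camera adjusted p 1.03e-09, but adjusted p = 0.520 with an estimated correlation). Cytosolic ribosomal proteins had 9 of 138 higher and 0 lower, or 1 adjusted over the list alone, such as RPS7B at 2.18 (median 0.72; camera adjusted p 7.56e-07, but adjusted p = 0.779 with an estimated correlation). Haploid-specific genes had 5 of 16 higher and 0 lower, as also adjusted over the list alone (median 0.69; camera adjusted p 0.00548, but adjusted p = 0.520 with an estimated correlation), such as RDH54 at 2.93. The samples of haploid BY4741 are at T6h alone. Ergosterol synthesis had 7 of 30 higher and 1 lower, or 8 and 1 adjusted over the list alone (median 0.37; camera adjusted p 0.0257, but adjusted p = 0.779 with an estimated correlation), with ERG3 at 3.20. The cell wall list had 12 of 41 higher and 4 lower, or 17 and 4 adjusted over the list alone (median 0.24; camera adjusted p 0.0357, but adjusted p = 0.520 with an estimated correlation), with the wall proteins PIR3 and CIS3 at 4.54 and 3.50. Among 7 sodium pump and arsenic genes, 2 fell and 0 rose, as also adjusted over the list alone (median -0.87; camera adjusted p 0.0159, but adjusted p = 0.351 with an estimated correlation), the pumps ENA2 and ENA1 at -3.31 and -2.77. TPO2, a polyamine exporter, was at 6.54 ± 0.54, and PET122, a mitochondrial translation activator, at 5.40.

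The remaining lists were not called (camera adjusted p 0.0565 to 0.940). Their medians were 0.59 for sucrose and maltose use, 1.03 for aquaporins, 0.46 for nitrogen catabolite repression, 0.45 for trehalose and glycogen, 0.34 for hexose transporters, 0.41 for oxidative stress and 0.51 for glycerol. They were 0.06 for alcohols and aldehydes, 0.31 for thiamine, -0.04 for pyridoxine, 0.09 for phosphate, 0.12 for iron, -0.06 for copper and zinc, 0.31 for drug export and 0.31 for the asparaginase cluster. For flocculation the median was 0.73, for histones -0.10 (mean of the other sign), for autophagy -0.16, for meiosis -0.13, for a-specific genes 0.33, for alpha-specific genes -0.05 (mean of the other sign) and for the deletion markers 1.42.

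With slide as a block, 715 genes passed, and on slide 1 alone 756. List medians were then 4.18 for glycolysis, -1.89 for oxidative phosphorylation, -1.92 for the TCA cycle, -2.72 for the glyoxylate cycle, -1.49 for peroxisomes, 1.61 for amino acids, 2.56 for sulfur, 2.00 for heat shock, 1.29 for seripauperins, -0.50 for ribosome biogenesis, 0.98 for ribosomal proteins, 0.68 for haploid-specific genes and 0.31 for ergosterol. The cell wall (0.39) and sodium pump (-1.07) lists were not called on slide 1 alone (camera adjusted p 0.0536 and 0.0649), but were with slide as a block (0.0402 and 0.0465). The count was 589 without PE-2 T0h replicate 1, 480 without JP1 T0h replicate 2 and 446 without CAT-1 T0h replicate 3. The calls of HXT4 (2.92) and RPP2A (1.73) were lost without T0h replicate 3 (adjusted p 0.0801 and 0.0893) or 2 (0.0657 and 0.0634). Those of PAU4 (2.05), RPF2 (-1.53) and STE18 (2.68) were lost without any 1 of the T0h arrays (up to 0.0785, 0.0968 and 0.121). On slide 1 alone PAU4 and STE18 were not called (0.0634 and 0.0719), and with the block PAU4 and RPF2 were not (0.0687 and 0.0587). STE18 was also lost without CAT-1 T6h replicate 2 (0.0554).

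**Figure D1:**
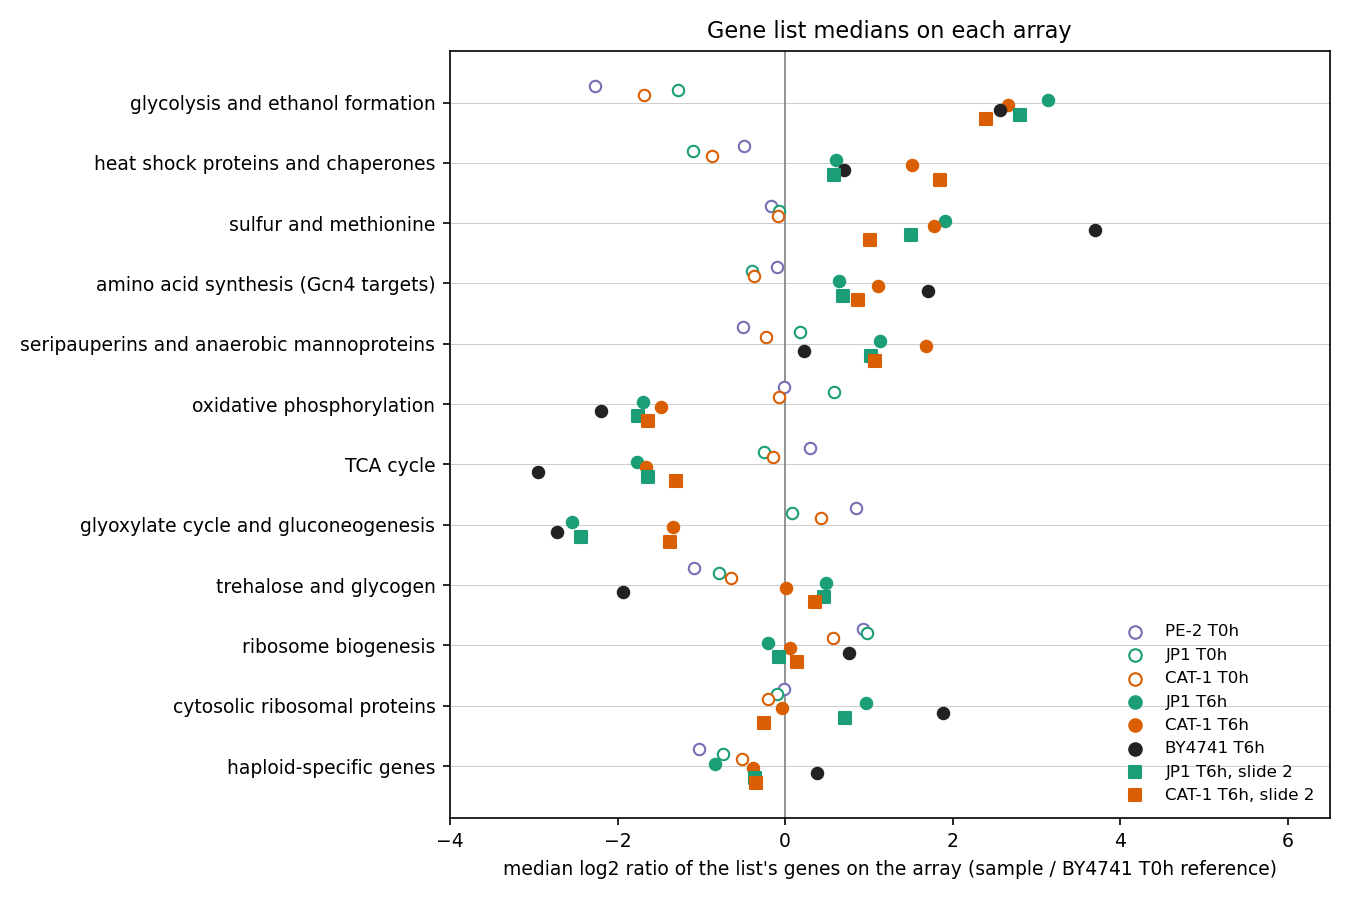
Median log2 ratio to the BY4741 T0h reference (x axis) of 12 gene lists (y axis) on each array, coloured by strain, with open symbols for T0h, filled ones for T6h and squares for slide 2. On the BY4741 T6h array the median of trehalose and glycogen genes was -1.93 and that of sulfur and methionine genes 3.70.

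In the strains seen at both times, JP1 and CAT-1, glycolysis genes rose and respiration genes fell as well, and 8 of 21 trehalose and glycogen genes rose. Haploid-specific genes had 2 of 16 higher and 0 lower, as also adjusted over the list alone, and were not called (median 0.39; camera adjusted p 0.123). ENO2, ENO1 and PDC1 rose by 6.65 ± 0.37, 6.64 ± 0.43 and 5.99 ± 0.31 (SE, 4 arrays against 2; limma adjusted p 3.29e-06, 7.50e-06 and 3.07e-06). HXK1, a hexokinase of glucose-poor cells, rose by 5.10 ± 0.39, and SIP18, linked to drying, fell by 5.19 ± 0.37. The comparison asked how the industrial strains change over 6 h with their differences in level removed: 755 genes rose and 414 fell, of which 1128 changed at least 2-fold, and 1981 had an unadjusted p under the threshold.

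Of 21 trehalose and glycogen genes, 8 rose and 1 fell, or 9 and 2 adjusted over the list alone (median 0.65; camera adjusted p 0.000624, but adjusted p = 0.341 with an estimated correlation). Glycogen phosphorylase gene GPH1 was at 2.97, PGM2 at 2.78 and UGP1 at 2.32, which make glucose phosphates and UDP-glucose. Among 4 aquaporins, 3 rose and 0 fell, as also adjusted over the list alone (median 1.60; camera adjusted p 0.00901, but adjusted p = 0.346 with an estimated correlation), with AQY3 at 1.73 and AQY2 at 1.48. Of 14 sucrose and maltose genes, 4 rose and 0 fell, as also adjusted over the list alone (median 0.60; camera adjusted p 0.0171, but adjusted p = 0.303 with an estimated correlation), with MAL33 at 1.06 and the invertase gene SUC2 at 0.98. Ergosterol synthesis had 11 of 30 higher and 1 lower, or 12 and 1 adjusted over the list alone, with ERG6 at 2.44 (median 0.67; camera adjusted p 0.00128, but adjusted p = 0.492 with an estimated correlation). Glycolysis had 20 of 21 higher and 0 lower, as also adjusted over the list alone (median 4.04; camera adjusted p 1.37e-21, but adjusted p = 0.188 with an estimated correlation). Heat shock genes had 23 of 34 higher and 4 lower, or 25 and 4 adjusted over the list alone, with BTN2 at 5.43 (median 2.34; camera adjusted p 6.50e-10, but adjusted p = 0.303 with an estimated correlation). Seripauperins had 19 of 30 higher and 0 lower, or 28 adjusted over the list alone, with TIR3 at 3.32 (median 1.23; camera adjusted p 2.13e-11, but adjusted p = 0.303 with an estimated correlation).

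Oxidative phosphorylation had 34 of 40 lower and 2 higher, or 36 and 2 adjusted over the list alone (median -1.79), the glyoxylate cycle 12 of 19 lower and 1 higher, or 16 and 1 alone (-2.02), the TCA cycle 9 of 17 lower, or 10 alone (-1.04), and peroxisomes 12 of 25 lower and 1 higher, or 13 and 1 alone (-0.86). Their camera adjusted p were 8.07e-20, 1.30e-10, 3.07e-05 and 3.31e-06, but each had adjusted p = 0.303 with an estimated correlation. CIT2, the citrate synthase of the glyoxylate cycle, was at -3.56. Amino acid genes had 36 of 62 higher and 4 lower, or 44 and 4 adjusted over the list alone (median 1.47, but -0.92 under the strict filter with 8 members; camera adjusted p 2.43e-11, but adjusted p = 0.188 with an estimated correlation). Sulfur genes had 24 of 36 higher and 0 lower, or 26 alone (median 1.79; camera adjusted p 1.42e-10, but adjusted p = 0.296 with an estimated correlation). Cell wall genes had 19 of 41 higher and 4 lower, or 20 and 5 alone (median 0.69; camera adjusted p 0.00705, but adjusted p = 0.355 with an estimated correlation). Ribosome biogenesis had 20 of 108 lower and 0 higher, or 22 alone, with RPF2 at -1.79 and CIC1 at -1.42 (median -0.71; camera adjusted p 4.61e-11, but adjusted p = 0.440 with an estimated correlation). Ribosomal proteins had 20 of 138 higher and 2 lower, or 9 and 2 alone (median 0.48; camera adjusted p 0.00266, but adjusted p = 0.676 with an estimated correlation), and were not called without JP1 T0h replicate 2 (median 0.06, adjusted p 0.679). Sodium pumps had 3 of 7 lower and 0 higher, as also alone (median -0.75; camera adjusted p 0.0309, but adjusted p = 0.303 with an estimated correlation).

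Among single genes, LEU2 and MET17, of leucine and methionine synthesis, rose by 4.74 ± 0.90 and 4.97 ± 0.94. URA3, of uracil synthesis, fell by 1.58 ± 0.35, and HIS3, of histidine synthesis, was at 0.54 ± 0.45 (limma adjusted p 0.440). The green BY4741 reference was not well above background for these genes on most arrays, so the sizes depend on green background. LEU2 red signals were 22738 and 18787 on JP1 T6h replicates 1 and 4, but its log2 ratios were 7.95 and 5.71. The copper transporters CTR3 and CTR1 were at -6.45 and -3.06, the phosphate transporter PHO84 at 2.28 and GRE1, linked to drying, at -4.17.

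With slide as a block 970 genes passed, and on slide 1 alone 715. List medians were then 4.40 for glycolysis, 0.65 for trehalose, 1.65 for aquaporins, 0.55 for sucrose and maltose, 0.86 for ergosterol, 2.26 for heat shock, 1.44 for seripauperins, -1.76 for oxidative phosphorylation, -1.93 for the glyoxylate cycle, -1.16 for the TCA cycle, -1.12 for peroxisomes, 1.53 for amino acids, 2.05 for sulfur, 0.93 for cell wall, -0.75 for ribosome biogenesis and 0.47 for ribosomal proteins. The sodium pump list (-0.21) was then not called (adjusted p 0.0878 with the block, 0.157 on slide 1), and the deletion markers (3.72) were (0.0157 and 0.0341). On slide 1 alone the calls of AQY2, CIC1, MAL33, RPF2, SUC2 and URA3 were lost (adjusted p 0.0514, 0.0530, 0.0668, 0.0520, 0.0700 and 0.0735), and MAL33 also with the block (0.0892).

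Without JP1 T0h replicate 2 the count was 417, and without CAT-1 T0h replicate 3 it was 578. Without the former array adjusted p were 0.0615 for LEU2, 0.0827 for MET17, 0.0540 for URA3, 0.0929 for AQY2, 0.214 for CIC1, 0.240 for RPF2, 0.160 for MAL33 and 0.315 for SUC2. Without the latter they were 0.0788 for LEU2, 0.0608 for MET17, 0.150 for URA3, 0.128 for AQY2, 0.103 for AQY3, 0.299 for MAL33 and 0.120 for SUC2. The SUC2 call was lost without any of the T6h arrays too (0.0780, 0.0881, 0.0551 and 0.0568 without replicates 1, 2, 4 and 5), and that of MAL33 without replicates 1, 2 and 5 (0.0819, 0.0665 and 0.103).

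**Figure D2:**
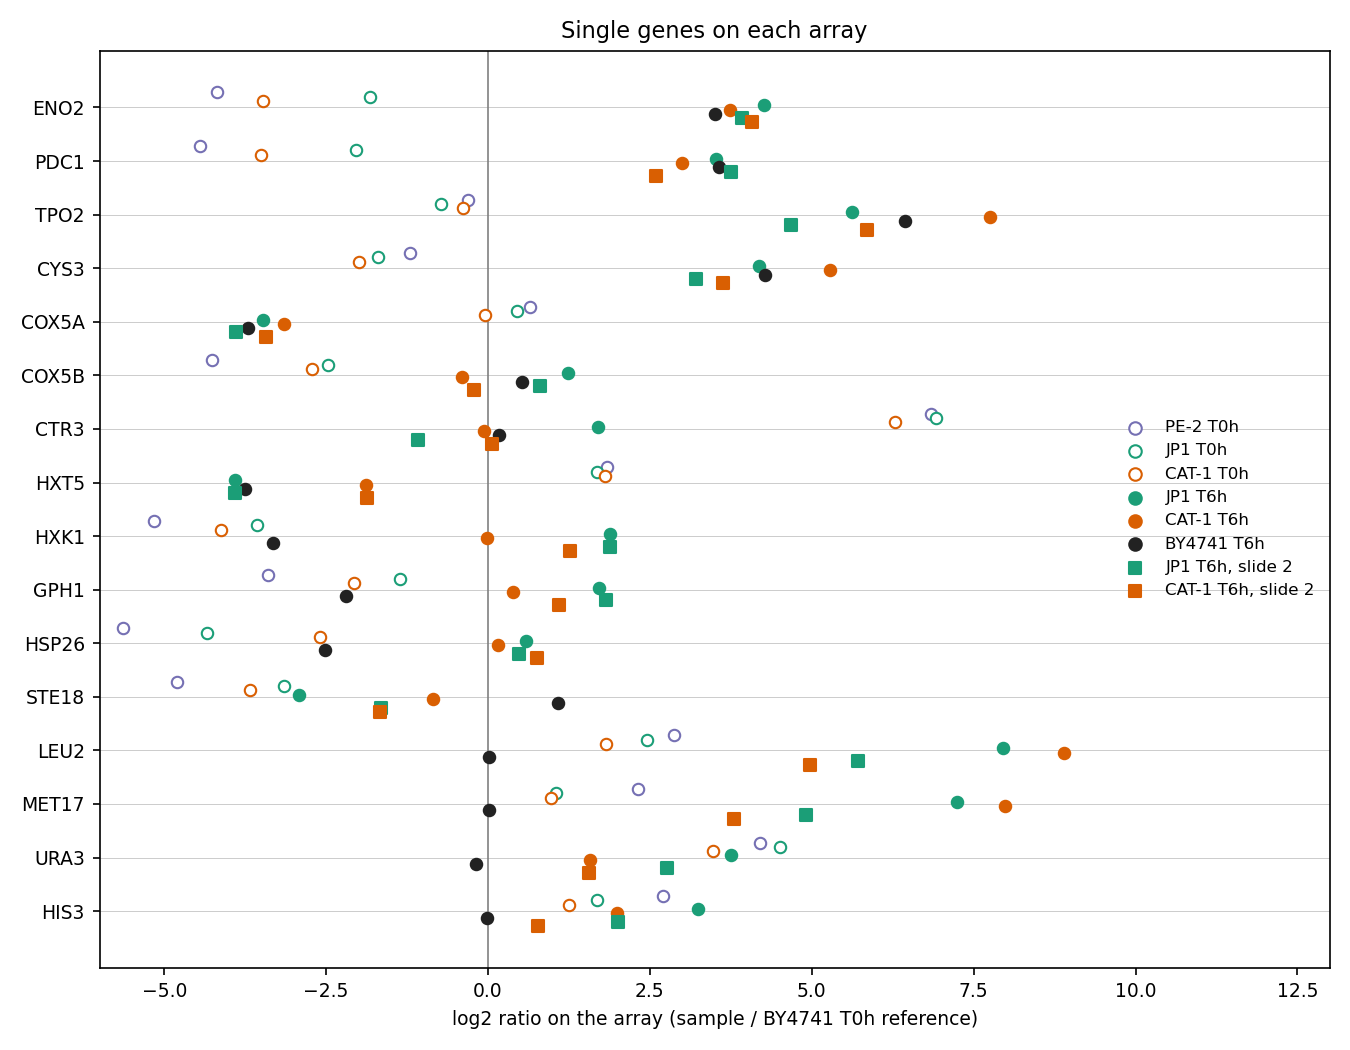
Log2 ratio to the BY4741 T0h reference (x axis) of 16 genes (y axis) on each array, coloured by strain, with open symbols for T0h, filled ones for T6h and squares for slide 2. CTR3 was higher at T0h than at T6h by 6.68 against 0.16 on average, and LEU2 was at 0.02 on the BY4741 T6h array.

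At the start of fermentation the industrial strains differed from BY4741 in the lists of ribosome biogenesis, glycolysis, trehalose and glycogen and haploid-specific genes, among others. These are camera calls at the preset correlation, and 0 lists were called with an estimated correlation or with fry on balance. The copper and zinc list was not called (median -0.10; camera adjusted p 0.573). CTR3 was higher in the industrial strains by 6.68 ± 0.19 (SE, 3 arrays; limma adjusted p 5.33e-05), and the intron-encoded gene AI5_ALPHA of the mitochondrial genome was lower, at -5.02 ± 0.32 (0.000822). URA3 was at least 15.3-fold, LEU2 at least 4.75-fold, HIS3 at least 3.36-fold and MET17 at least 2.36-fold higher, since the BY4741 reference gave no signal well above background for these genes that it lacks. Of 5938 genes, 902 were higher and 1037 lower, of which 773 differed at least 2-fold, and 2643 had an unadjusted p under the threshold. The comparison asked how the industrial strains differ from the laboratory strain before fermentation. In it the dye differs along with the strain. No BY4741 sample of T0h was set against the reference, so the SE and p leave out the spread of BY4741.

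Of 108 ribosome biogenesis genes, 77 were higher and 1 lower, or 88 and 2 adjusted over the list alone (median 0.85; camera adjusted p 4.04e-18, but adjusted p = 0.758 with an estimated correlation), such as DBP2 at 1.55, CIC1 at 1.42 and ARX1 at 1.39. Glycolysis had 16 of 21 lower and 0 higher, or 18 adjusted over the list alone (median -1.82; camera adjusted p 1.38e-08, but adjusted p = 0.758 with an estimated correlation), with PDC1 and TDH1 at -3.33 each and ENO2 at -3.16. Of 21 trehalose and glycogen genes, 13 were lower and 1 higher, as also adjusted over the list alone (median -0.92; camera adjusted p 0.000513, but adjusted p = 0.758 with an estimated correlation), with GPH1 at -2.28, TPS1, of trehalose synthesis, at -1.97 and the glycogen synthase gene GSY2 at -1.81. HXK1 was at -4.29 and REE1, a regulator of enolase, at -3.84.

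Haploid-specific genes had 10 of 16 lower and 1 higher, as also adjusted over the list alone (median -0.75; camera adjusted p 0.000280, but adjusted p = 0.758 with an estimated correlation). STE18, a G protein subunit of the pheromone response, was at -3.88, RME1, a repressor of meiosis, at -3.83, NEJ1, of DNA end joining, at -2.15, and the scaffold gene STE5 at -2.02. Of the a-specific genes, 3 of 7 were lower, as also alone, with ASG7 at -1.62, MFA2 at -1.38 and the pheromone receptor STE2 at -0.52 (adjusted p 0.0821), and the list was not called (median -0.57; camera adjusted p 0.0594). IME4, a promoter of meiosis, was at 3.21. All 4 deletion markers were higher, as also alone (median 2.13, or 2.00 with each at its bound; camera adjusted p 0.00136, but adjusted p = 0.758 with an estimated correlation).

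Heat shock genes had 20 of 34 lower and 5 higher, or 22 and 6 adjusted over the list alone (median -0.77; camera adjusted p 0.00136, but adjusted p = 0.758 with an estimated correlation), with HSP26 at -4.19, BTN2 at -3.04, SSA4 at -2.94 and SSE1 at -2.65. Sucrose and maltose genes had 8 of 14 lower and 0 higher, or 9 and 1 alone (median -0.89; camera adjusted p 0.00201, but adjusted p = 0.758 with an estimated correlation), with the isomaltase genes IMA3 and IMA2 at -1.86 and -1.73 and SUC2 at -1.55. The asparaginase II genes, such as ASP3-1 at -1.54 and ASP3-4 at -1.52, were lower in 4 of 4 cases, as also alone (median -1.52; camera adjusted p 0.00456, but adjusted p = 0.758 with an estimated correlation). Whether the probes tell these gene copies apart was not tested, so the 4 cases may not be separate, here or at T6h. The same goes for CUP1-1 and CUP1-2 and for other closely related genes named below, such as HXT6 and HXT7. Genes under nitrogen catabolite repression had 16 of 34 lower and 1 higher, as also alone (median -0.53; camera adjusted p 0.00180, but adjusted p = 0.758 with an estimated correlation), with the ammonium permease gene MEP2 at -1.84. Amino acid genes had 19 of 62 lower and 3 higher, or 19 and 4 alone (median -0.41, or -0.06 under the strict filter with 8 members, where camera turned upward; camera adjusted p 0.0102, but adjusted p = 0.793 with an estimated correlation), with GDH1, of glutamate synthesis, at -3.49, GDH3 at -1.98 and ASN1 at -2.74. Alcohol and aldehyde genes had 11 of 24 lower and 2 higher, or 14 and 4 alone (median -0.62; camera adjusted p 0.0223, but adjusted p = 0.758 with an estimated correlation), with SFA1 at 3.12 and ADH6 at -2.46. Peroxisomal genes had 11 of 25 higher and 1 lower, as also alone (median 0.30; camera adjusted p 0.0222, but adjusted p = 0.762 with an estimated correlation), with the catalase gene CTA1 at 1.77 and POX1 at 1.41. Seripauperins had 5 of 30 lower and 0 higher, as also alone (median -0.15; camera adjusted p 0.0487, but adjusted p = 0.857 with an estimated correlation), with TIR1 at -2.82.

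Other single genes were PHO89, a phosphate transporter, at -4.47, COX1 and COB, of the mitochondrial genome, at 3.85 and 2.86, CIT3 at 2.83, SUE1 at 2.78, SPG1 at 2.35, and the metallothionein genes CUP1-1 and CUP1-2 at -3.28 and -3.30. All T0h arrays lie on slide 1. Without CAT-1 T0h replicate 3 the count was 538, and the calls of COX1, SPG1, GSY2, CUP1-1 and CUP1-2 were lost (adjusted p 0.0729, 0.0542, 0.0670, 0.111 and 0.112).

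At 6 h the industrial strains and BY4741 differed by large values in single genes, none of which passed the test. LEU2 was at least 116-fold and MET17 at least 62.5-fold higher in JP1 and CAT-1 (adjusted p 0.0603 and 0.0801), URA3 at least 6.06-fold (0.180) and HIS3 at least 4.05-fold (0.266). HXK1 was at 4.58 ± 0.71, PGM2 at 4.14 ± 0.48, CYC7, a cytochrome c form of low oxygen, at 3.86 ± 0.57, and RPS12, a ribosomal protein gene, at -3.38 ± 0.48 (SE, 4 arrays against 1; limma adjusted p 0.0603, 0.0542, 0.0555 and 0.0542). The comparison asked how the strains differ during fermentation: 0 of 5938 genes passed in limma, 895 had an unadjusted p under the threshold, and the smallest adjusted p was 0.0542. The single BY4741 array is assumed to vary like the others.

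Of 138 ribosomal protein genes, 135 had negative values, and 79 were lower adjusted over the list alone (0 over all genes; median -1.57; camera adjusted p 3.88e-37, but adjusted p = 0.339 with an estimated correlation). All 21 trehalose and glycogen genes had positive values, and 17 were higher adjusted over the list alone (median 2.10; camera adjusted p 6.91e-17, but adjusted p = 0.339 with an estimated correlation), with GPH1 at 3.45. The medians of ribosome biogenesis (-0.77), amino acids (-0.97), sulfur (-1.21) and seripauperins (1.00) had camera adjusted p 3.77e-12, 1.56e-10, 1.56e-10 and 4.64e-10, with 0, 16, 15 and 2 members passing adjusted over the list alone, but adjusted p = 0.339 with an estimated correlation for each. MET14 and MET3, of sulfate assimilation, were at -3.59 and -3.10, and YCT1, a cysteine transporter, at -3.28. The TCA cycle (1.26; 9 higher and 1 lower alone), oxidative phosphorylation (0.50; 3 higher alone), the deletion markers (4.28; 4 higher alone), oxidative stress (0.89; 4 higher and 1 lower alone), autophagy (0.54; 0 alone) and alpha-specific genes (-1.34; 3 lower alone) had camera adjusted p 1.13e-06, 0.000209, 0.000136, 0.00239, 0.00228 and 0.0451, but adjusted p = 0.339 with an estimated correlation for each. Haploid-specific genes (-0.82; 1 lower alone) and peroxisomes (0.88; 3 higher alone) had camera adjusted p 0.00239 and 0.000162, but adjusted p = 0.414 with an estimated correlation. STE18 and MFA2 were at -2.86 and -2.53. Heat shock (0.49; 3 higher alone) and ergosterol (0.65; 0 alone) had camera adjusted p 0.00192 and 0.00238, but adjusted p = 0.462 with an estimated correlation. The a-specific genes (-0.48; 1 lower alone), cell wall (0.38; 4 higher alone) and the asparaginase cluster (-1.11; 4 lower alone) had camera adjusted p 0.0165, 0.0131 and 0.00269, but adjusted p = 0.416, 0.374 and 0.384 with an estimated correlation. Hexose transporters HXT6 and HXT7, of high affinity, were at 3.30 and 3.37, HXK2, the hexokinase of glucose-rich cells, at -3.30, and CUP1-1 and CUP1-2 at -3.60 and -3.69.

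With slide as a block LEU2 was at 8.40 and MET17 at 7.60. BY4741 gave no signal well above background for either gene at T6h, so these sizes rest on background. The lists were also tested with that block and on slide 1 alone. List medians were then -1.42 for ribosomal proteins, 1.99 for trehalose, -0.77 for ribosome biogenesis, -0.97 for amino acids, -1.08 for sulfur, 1.11 for seripauperins, 1.11 for the TCA cycle, 0.70 for oxidative phosphorylation, 5.22 for the deletion markers, 0.79 for oxidative stress, 0.44 for autophagy, -1.16 for alpha-specific genes (not called on slide 1 alone, adjusted p 0.0601), -0.94 for haploid-specific genes, 0.69 for peroxisomes, 0.50 for heat shock, 0.92 for ergosterol, -0.58 for a-specific genes, 0.50 for cell wall and -0.95 for the asparaginase cluster. Hexose transporters (0.55) were then called (0.0359 with the block, 0.0392 on slide 1), and alcohols and aldehydes (0.31) with the block (0.0462). Without JP1 T6h replicate 1, 60 genes passed, among them HXK1, PGM2, CYC7, RPS12, MET3, CUP1-1 and CUP1-2 (adjusted p 0.0256 each), LEU2 (0.0280), MET14 (0.0276), HXK2 (0.0283), GPH1 and HXT6 (0.0323 each) and YCT1 (0.0326). Without CAT-1 T6h replicate 2, 1 passed, HXK1 at 5.00 (0.0353).

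CAT-1 and JP1 differed in a few genes over both times. CSS3 and AYT1, an acetyltransferase for a fungal toxin, were at least 7.60-fold and 5.56-fold higher in CAT-1, where JP1 gave no signal well above background (limma adjusted p 0.00209 and 0.00404). YAT1, which makes carnitine esters in mitochondria, was higher by 4.50 ± 0.59 (SE, 3 arrays against 3; 0.0163), and the chaperone gene SSA3 by 2.02 ± 0.31 (0.0455). COX3 and ATP6, of the mitochondrial genome, were at -3.00 ± 0.29 (0.00209) and -2.64 ± 0.36 (0.0207). The comparison asked how the strains differ whatever the time: 4 genes were higher and 2 lower, all at least 2-fold, and 903 had an unadjusted p under the threshold.

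Ribosomal protein genes had negative values in 128 of 138 cases, with 0 passing over all genes or adjusted over the list alone (median -0.64; camera adjusted p 4.27e-22, but adjusted p = 0.487 with an estimated correlation). Heat shock genes had 1 of 34 higher, or 19 higher and 2 lower adjusted over the list alone (median 1.09; camera adjusted p 2.20e-07, but adjusted p = 0.471 with an estimated correlation). Peroxisomal genes had 1 of 25 higher, or 7 alone (median 0.48; camera adjusted p 1.88e-05, but adjusted p = 0.471 with an estimated correlation). In the other called lists 0 passed over all genes. The glyoxylate cycle (1.00; 12 higher alone), phosphate (0.33; 3 higher alone), nitrogen catabolite repression (0.26; 3 higher alone), oxidative stress (-0.25; 1 higher and 2 lower alone) and amino acids (0.30, but -0.12 under median centring; 0 alone) had camera adjusted p 6.51e-09, 0.000537, 0.0235, 0.0466 and 0.0192, but adjusted p = 0.471 with an estimated correlation for each. Ergosterol (-0.52; 1 higher and 8 lower alone), the TCA cycle (0.23, but -0.50 under median centring; 1 higher alone) and glycolysis (-0.23; 2 higher and 7 lower alone) had camera adjusted p 3.73e-06, 0.0476 and 0.0476, but adjusted p = 0.487 with an estimated correlation for each. Oxidative phosphorylation (-0.13; 2 lower alone) and drug export (0.41; 1 higher alone) had camera adjusted p 0.0496 and 0.0235, but adjusted p = 0.745 and 0.591 with an estimated correlation. ADH2, the ethanol-using dehydrogenase, was at 2.56, FLO11, of adhesion, at 2.00, and the permease genes GAP1 and BAP2 at 1.72 each (adjusted p 0.0797, 0.0792, 0.0797 and 0.119), none of which passed, nor did COS12 at -2.48 and ZNF1, at least 3.62-fold lower (0.0521 each).

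With slide as a block 8 genes passed, COS12 among them (adjusted p 0.00745), and the glycolysis list was not called (0.0529) while the deletion markers were (median -0.56; 0.0372). On slide 1 alone 0 genes passed in limma, and adjusted p were 0.200 for CSS3, 0.201 for COX3, 0.288 for AYT1, 0.369 for ATP6 and 0.457 for YAT1 and SSA3. With the block, list medians were those over both slides. On slide 1 alone they were -0.49 for ribosomal proteins, 0.71 for heat shock, 0.40 for peroxisomes, 0.79 for the glyoxylate cycle, 0.45 for phosphate, 0.24 for nitrogen catabolite repression, 0.21 for amino acids, -0.65 for ergosterol, -0.36 for glycolysis and -0.21 for oxidative phosphorylation, and the TCA cycle (0.23), oxidative stress (-0.24) and drug export (0.21) were not called (adjusted p 0.119, 0.0812 and 0.0812).

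Without CAT-1 T6h replicate 5, 0 genes passed in limma and 481 had an unadjusted p under the threshold (adjusted p 0.0776 for CSS3 and COX3, 0.0886 for AYT1, 0.335 for YAT1, SSA3 and ATP6). Without CAT-1 T6h replicate 2, 3 genes passed (0.0535 for ATP6, 0.0906 for YAT1, 0.120 for SSA3), and without JP1 T6h replicate 4 the calls of YAT1 (0.0962) and SSA3 (0.127) were lost. Without JP1 T6h replicate 1, 12 passed, COS12 and ZNF1 (0.0418 each) and FLO11 (0.0357) among them. Without JP1 T0h replicate 2 or CAT-1 T0h replicate 3, which leaves T6h arrays to decide, 106 passed, with ADH2 at 3.61 (0.00453), BAP2 at 2.44 (0.0174) and GAP1 at 2.19 (0.0281) among them. Whether the time change differed between CAT-1 and JP1 was tested as well: 0 genes passed in limma, 341 had an unadjusted p under the threshold, and the smallest adjusted p was 0.330. With slide as a block 0 passed, without JP1 T6h replicate 1 31 passed, and without JP1 T6h replicate 4 50 passed.

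BY4741 itself was seen at both times only as the T0h reference and 1 array at T6h, so its change has no test. The dye differs along with the time in it. Sulfur and methionine genes had a median of 3.70, ribosomal proteins of 1.89, glycolysis of 2.56, amino acids of 1.70, ribosome biogenesis of 0.77 and heat shock of 0.71, each at the 100 percentile of 10000 random lists of like intensity. The TCA cycle (-2.95, percentile 0.01), glyoxylate cycle (-2.73), oxidative phosphorylation (-2.20), trehalose and glycogen (-1.93) and peroxisomes (-1.54) lay at the lowest percentile, 0, where no other is given. The random lists draw genes independently, while the genes of a list can move together, so these percentiles may overstate how far the lists stand out. In all, 1704 genes differed at least 2-fold, 925 higher and 779 lower, and under median centring 1841, 809 higher and 1032 lower. Of the 1169 genes that changed in JP1 and CAT-1 over time, 70.5% had the same sign in BY4741, against 57.1% of all genes (Pearson 0.417 across genes).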

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

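The test of time changes between strains and the tests of the haploid-specific and storage sugar patterns were chosen only after the results were seen, while those of the ribosomal protein pattern and the splits of the arrays were written before.

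Among the 5 T6h arrays the BY4741 array lay far from the other 4 for 3 of 37 list medians tested, against about 1 in 20 groups by chance, for 8 of 83 genes and for 0 of 6 array measures. That rate of chance takes the 5 arrays as independent and alike, but the other 4 are pairs of JP1 and CAT-1. The count of lists can therefore not be judged by it. Nor does it apply to the genes, since some of them were named for differing from BY4741. Its log2 ratios were -3.18 for SDH2, of the TCA cycle and respiration, -2.52 for HSP26, -1.94 for TIR1, -2.67 for PGM2, -1.34 for UGP1, -1.54 for CYC7, 1.79 for RPS12 and 3.27 for HXK2. Its list medians were -2.95 for the TCA cycle (others -1.76 to -1.30), -1.93 for trehalose and glycogen (others 0.01 to 0.49) and -0.57 for autophagy (others -0.01 to 0.12).

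The change over time differed between JP1 and CAT-1 on one side and BY4741 on the other for 709 genes (limma, 7 arrays; 398 higher and 311 lower, 1739 with an unadjusted p under the threshold). HXK1 had the smallest adjusted p, 0.000142, with a difference of 8.42 ± 0.59, at 5.10 in JP1 and CAT-1 and -3.32 in BY4741. HSP26, PGM2, GPH1 and TIR1 differed by 6.48, 5.45, 5.17 and 4.42. A bias of single genes to one dye cancels in the change of JP1 and CAT-1 but not in that of BY4741. The 709 genes may therefore include differences due to dye. The BY4741 side is 1 array, with its T0h level set to 0 by the reference and its spread taken from the other strains, and the direct comparison at T6h gave 0 genes in limma, with 895 at an unadjusted p under the threshold. Of 37 lists, 17 were called by camera and 0 with an estimated correlation. Among those called, 6 had medians of opposite sign in the strains. Their median differences were 2.72 for trehalose and glycogen, -1.49 for ribosome biogenesis, 1.19 for sucrose and maltose use, 0.69 for oxidative stress, 0.53 for glycerol and 1.71 for aquaporins (camera adjusted p 2.43e-14, 5.56e-21, 0.000200, 0.0416, 0.0450 and 0.00532, but adjusted p = 0.346 with an estimated correlation for each).

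Trehalose and glycogen genes, with 14 of 21 passing, had a median of -1.93 on the BY4741 T6h array, but of 0.65 in JP1 and CAT-1 over time, and ribosome biogenesis genes did the opposite, at 0.77 and -0.71. A bias of single genes to one dye, or a difference in level at T0h alone, would leave no difference between the strains at T6h, where dye and reference cancel. The difference there was 2.10 for trehalose and glycogen and -0.77 for ribosome biogenesis, where no single member passed adjusted over the list alone. With an estimated correlation, camera gave adjusted p = 0.339 for each list. Both values rest on the BY4741 T6h array, whose values also served to pick these lists. They argue against both explanations as the whole cause only as far as that array can be relied on. Since only 1 BY4741 array exists at T6h, a peculiarity of that culture or array cannot be told apart from a property of the strain. The strain, which the design names, stays among the open explanations as untested.

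Haploid-specific genes were lower in the industrial strains than in BY4741 at T0h, with 10 of 16 passing. A dye bias of these genes would lower them on the BY4741 T6h array too, where the list median was 0.38, but 1 array leaves it open. Repression of these genes in diploid cells, as the labels call the industrial strains, predicts that the list is lower at T6h as well, and its median difference there was -0.82. Weaker hybridisation of diverged sequences predicts the same, so it cannot be told apart from that repression, which is 1 hypothesis consistent with the values. The 1 list member that was higher at T0h was MATALPHA1, of the alpha mating type that BY4741 lacks. It goes against the direction that such repression predicts, and why it was higher was not tested.

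Cytosolic ribosomal protein genes were called lower in CAT-1 than in JP1 as a list by camera at the preset correlation, with no single member passing. With an estimated correlation, or with fry on balance, 0 lists were called in this comparison. The weak green channel of slide 2 is argued against as the whole cause, since on slide 1 alone the median difference was -0.49, against -0.64 over both slides. A low red signal on the CAT-1 T6h arrays remains open: at T0h, where the CAT-1 red signal was the brighter, the median difference was -0.11, with 91 of 138 members negative, against -0.90 at T6h. The strain itself, named by the design, stays among the open explanations.

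Among all 56 splits of the 8 arrays into 3 and 5, only 1, the real one, gave as many as 929 genes, and the highest of the others gave 75, so chance can be excluded for that count if the 8 arrays are independent samples. If the T6h pairs of JP1 and CAT-1 hold the same RNA, 3 samples against 3 remain, whose 10 splits are too few for a share under the threshold, and with these pairs averaged 684 genes passed. For the 6 genes between CAT-1 and JP1, the 10 splits are too few for a share under the threshold: 2 gave as many, the real one included, and the highest other gave 7.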

How the results depend on the processing

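The red channel alone, the averaging of the T6h arrays of 1 strain, slide settings for the comparison with BY4741 and for the lists, and lists with arrays left out were chosen after seeing the data.

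The count over all 8 arrays (929) was 439 under median centring, 292 under the strict filter, which tests 679 genes, and 1556 in the red channel, where 46.5% of the called genes rose, against 62.1%. Under the strict filter 107 rose and 185 fell. Leaving out 1 array gave 446 to 1128. In JP1 and CAT-1 over time (1169, 64.6% rising) it was 509 without background subtraction, 565 with processed signals, 339 under median centring, 375 under the strict filter (160 rising, 215 falling), 715 on slide 1 alone (fewer arrays) and 2300 in the red channel (48.2% rising). Leaving out 1 array gave 417 to 1169. The count at T0h (1939) was 252 under the strict filter and 773 at least 2-fold, and 538 to 1929 with 1 array left out. The count between the strains at T6h (0, with 895 at an unadjusted p under the threshold in limma) was 33 under the strict filter, 4 with the trend and robust prior, 2 with slide as a block, 20 in the red channel and 2 with arrays averaged, and 0 to 60 with 1 array left out. Between CAT-1 and JP1 (6) it was 0 without background subtraction, 1 with processed signals, 3 under median centring, 39 under the strict filter, 10 with the trend and robust prior, 0 on slide 1 alone, 106 at T6h alone, 173 in the red channel and 37 with arrays averaged, and 0 to 106 with 1 array left out. The difference of their time changes (0, with 341 unadjusted) gave 41 under the strict filter and 253 in the red channel, and 0 to 50 with 1 array left out. Genes at least 2-fold in BY4741 (1704) were 2557 with processed signals. With median centring 43.9% of those in BY4741 were higher, against 54.3%. Apart from the smaller sets of genes or arrays, the cause was not tested.

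Replicate number as a block gave 536 genes over all 8 arrays. The numbers do not pair the samples, and same-number pairs are of different strains. The deviations of their log ratios from the mean of their time correlated at -0.151 to -0.0733. By these deviations, 0 of 6 samples correlated best with its own number. In JP1 and CAT-1 that block could not be fitted.

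Called lists were 15 over all arrays, 17 in JP1 and CAT-1, 13 at T0h, 19 between the strains at T6h and 13 between CAT-1 and JP1. With an estimated correlation each count was 0, and under the strict filter they were 8, 8, 8, 7 and 5. With fry on balance, the last 3 gave 0, 1 and 0. With fry mixed, the first 3 and the last gave 29, 32, 36 and 4. Leaving out 1 array gave 13 to 19, 16 to 19, 13 to 14, 19 to 20 and 9 to 15.

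The median of all genes moved by over 0.1 with processed signals in JP1 and CAT-1 over time (by 0.11), between the strains at T6h (0.18), between CAT-1 and JP1 (-0.11) and in the difference of time changes (-0.19). It moved with median centring in that difference (-0.15), in the red channel over time (-0.12 over all arrays, -0.13 in JP1 and CAT-1) and in the difference (-0.15), and with the fewer genes of the strict filter (-0.26 and -0.24 over time, -0.23 at T0h, 0.23 at T6h). For the 162 single genes, 2574 of 2761 alternative values kept their direction and side of the threshold, 131 kept only their direction (95 higher, 36 lower), 56 newly passed and 0 reversed. Values under quantile scaling were counted among these, though it leaves the log ratios as they were. Between CAT-1 and JP1, leaving out either T0h array gives the same fit as the T6h arrays alone, yet each was counted. Many of the genes were named for passing, so the share overstates how stable they are. Of 54 genes over all 8 arrays, 52 had an exact permutation p under the threshold, and 45 had the smallest possible, 0.0179. The largest was 0.0536, for PAU4 and STE18. These p also take the 8 arrays as independent samples. The genes were named for passing the same comparison, so low permutation p follow largely from that choice and add no support.

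Not run were the deposited value table, most of whose columns do not follow their own arrays, and the mean over probes, as each gene has 1 probe. Slide 1 alone left no spare arrays for the difference of time changes. Quantile scaling left the log ratios, and so the results, as they were. The weak green signal of slide 2 limits JP1 T6h replicate 4 and CAT-1 T6h replicate 5 most.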

Other observations

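The test of whether neighbouring genes stay low at T6h was chosen only after the result was seen, and the test of their number was written before.

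Genes measured on the industrial strains at T0h and T6h against the same reference gave differences from BY4741 at T0h and T6h that were hardly related over all genes. Across the 5938 genes, which are not independent replicates, these had a Pearson correlation of -0.0459, and 43.1% of the 1939 genes that differed at T0h had the same sign at T6h, as did 44.8% of all genes. The T0h difference correlated at 0.181 with the BY4741 T6h array, with the same sign for 67.5% of the 1939 and 60.7% of all genes. Both share the reference and the dye, so a common part in these values is not excluded. The 4 deletion markers were higher at both times.

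Genes lower by at least 2 on the log2 scale in the industrial strains at T0h may lie in segments that those strains lack. Among 66 such genes there were 3 pairs of neighbours, YER152C with PET122, SPL2 with ARO9, and ADH6 with FET4, against a mean of 0.762 and a highest of 6 in 10000 random sets of the 5649 genes in order (permutation p 0.04). Absent genes would stay low at T6h, but on the JP1 and CAT-1 T6h arrays they went both ways. PET122 was at 3.36, FET4 at 0.16, YER152C at -0.50, ADH6 at -0.74, SPL2 at -1.51 and ARO9 at -3.86, with a median of -0.62. PET122 was thus expressed in those strains. Set against BY4741 at T6h, the genes in these pairs differed by a median of 0.24, from -0.39 for ADH6 to 1.19 for SPL2. SPL2 and ARO9 stayed low against the reference, and BY4741 was measured at T6h on 1 array, so for the set absence or divergence stays open. These genes were picked after their values were seen.

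The deposited value table has 8 columns, of which 3 correlated best across genes with the array they are named for. The column named for JP1 T0h followed JP1 T6h replicate 1 with a slope of 0.9996, and that for CAT-1 T0h followed CAT-1 T6h replicate 2 with a slope of 0.9998. The column named for JP1 T6h replicate 1 followed the mean of that array and the BY4741 T6h array (0.9997), and that for CAT-1 T6h replicate 2 the mean of the PE-2 and JP1 T0h arrays (0.9994). The column of PE-2 T0h correlated best with the BY4741 T6h array, at 0.358. Those of BY4741 T6h and of T6h replicates 4 and 5 correlated with their own arrays at 0.979, 0.999 and 0.992, with slopes of 0.589, 0.9987 and 0.997. All values here follow the names of the scanner files. The BY4741 T6h array had no red signal well above background for the 4 deletion markers, which the other 7 arrays had, and correlated at 0.487 to 0.638 with T6h arrays and at 0.107 to 0.198 with T0h arrays. The other strain names rest on the labels. A mean of 2 arrays is no single sample, so wrong file names cannot account for the columns that followed such means. For the other columns, which of the table or the files is misnamed is not given. Column medians were 0.0078, -0.015 and -0.023 at T0h and -0.0017, 0.0028, -0.011, -0.039 and -0.055 at T6h, in the order of replicates.

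In the red channel alone, the 2 JP1 T6h arrays correlated at 0.984 across genes and the 2 CAT-1 T6h arrays at 0.957, against 0.716 to 0.935 for arrays of different strains. Whether each pair holds the same RNA is not given.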
